A study of Capra hircus with 24 samples.

How the data were processed

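RNA of 8 healthy female goats in 3rd lactation was measured on 24 two-colour Agilent arrays, 4 goats of the Polish White Improved breed (PWI) and 4 of the Polish Fawn Improved breed (PFI). Each goat gave RNA from 3 sources, which are milk somatic cells (MSC, the cells shed into milk), peripheral nuclear cells of blood (PNCB) and milk fat globules (MFG, lipid droplets that carry cytoplasm of the secreting cell). The 6 groups of source and breed hold 4 arrays each. Per the labels, the sample was labelled with Cy5 on every array and the common reference with Cy3, with no dye swap, so a dye effect cannot be separated from the sample but is shared by all arrays. The reference was a pool of blood nuclear cell RNA from 7 goats in 4th lactation, 4 PWI and 3 PFI. Per the labels' protocols, RNA of both milk sources was extracted with one kit and RNA of blood with another, so kit and source cannot be told apart in any comparison with blood. The array was designed for cattle, with build UMD 3.1 / bosTau6 named in the file headers, and was hybridised here with goat RNA. A probe whose cattle sequence differs from the goat's can read low, and one that differs between breeds can read as a breed difference.

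The scanner files hold median spot and local background intensity in both channels, made with Agilent Feature Extraction 10.7.3.1 per the file headers and with no normalization. The same files hold, per the file headers, 0 or 1 flags per spot and the software's processed signals, which are background subtracted and dye normalized. The authors' deposited table holds log10 ratios of Cy5 over Cy3 and equals the software's own log ratio in every spot of every array (largest difference 0), so its scale and direction are known. In that table between 2.64% and 31.4% of the spots of an array stand at exactly 0.

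The values used here were made from the intensities with R 4.3.3 and limma 3.58.1. Each array has 45220 spots, of which 43803 are not controls and make up 43653 probes. Spots with any outlier flag were left out, the background was corrected with normexp (offset 50), and ratios were normalized within each array by loess, with control spots given no weight. Spots of one probe were averaged. The design fixed beforehand named normexp and loess but not when flagged spots leave. A first look kept all flagged spots, and the order used was settled after its counts, with 0 breed calls in each fit of 8 arrays, had been seen. With all spots in the normexp fit, the fitted background mean was as low as -391 and more than 50 below 0 on 7 arrays, against a lowest of -5.29 in the order used. All 76 spots with a net signal below -20 were flagged, but their removal alone was not tested. The effect of this decision on each count stands with the alternatives. No spot was saturated.

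A probe was tested if its Cy5 signal was well above background on all 4 arrays of at least 1 of the 6 groups, which left 27411 probes of 16830 accessions. The files pair probes with cattle transcript accessions and with no gene symbols, and 0 of 26748 accessions matched the goat gene table provided (assembly ARS1.2). Gene names are therefore not given, and the gene lists and list tests fixed beforehand were not run. The rule fixed for named genes was applied to probes without its requirement of a symbol. It takes probes past the threshold that differed at least 2-fold, with the same sign in all 8 goats and well above background on all 8 arrays of the brighter source, in order of fold, one probe per accession (its brightest). With no names, at most 2 probes per direction are printed for each comparison of sources. Breed calls are few and are all named, so those names were chosen after their values were seen. Some named probes were not well above background on any array of the dimmer source. For these the fold measured in the Cy5 channel after loess and Aquantile is given beside that of the ratios. It is not a ratio to the reference and is no bound, as the dimmer signal lay near background. It also differs from the alternative called Cy5 alone, which uses no loess.

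Sources were compared in one limma fit (lmFit and eBayes) of 24 arrays with 6 group means, each contrast averaging both breeds. Breeds were compared within each source on 8 arrays, over all sources with 1 mean per goat, and as an interaction with source by an F-test on 24 arrays. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. A log2 difference is that of the ratios to the reference. The test was also run on the Cy3 channel, which held the same reference on every array.

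Per the array file names each of the 6 groups lies on its own slide, so slide and breed cannot be told apart within a source, and a source spans 2 slides. All MFG arrays were scanned on a different day from the MSC and PNCB arrays, so scan day and MFG cannot be told apart. The goat number is also the array's position on its slide. Goats carry the same number in all sources and the labels name 4 goats per breed, so equal numbers within a breed pair samples of one animal. Deviations from the group means correlated across probes at a mean of 0.126 between the MSC and PNCB arrays of a goat, 0.0242 between MFG and PNCB and -0.0329 between MFG and MSC (8 pairs each), and 6, 4 and 2 of the 8 arrays correlated best with their own goat. Across breeds a number marks no shared animal, though it does mark the same slide position.

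Precision is limited by the number of arrays and by signal over background. Spike-in controls gave an observed over expected slope of 0.758 to 0.887 on 21 arrays and of less than 0.7 on 3 arrays, all of PWI goats. These were PNCB goat 3 (slope 0.645), PNCB goat 4 (0.567, with 21.2% of spots flagged) and MFG goat 2 (0.489, with a median Cy5 signal of 69 on negative controls). Counts without these 3 arrays were added after seeing the data. The fit was tested on simulated data with 200 changed probes. The simulation first gave each probe its own SD in each source, and as the share of false calls was then too high for the threshold, one SD per probe pooled over the sources was used instead for the source and interaction tests. With the pooled SD, the source comparisons recovered 72% to 82% of 2-fold and 100% of 4-fold changes with 4.12% to 5.92% false calls. The breed comparisons within a source, simulated with the SDs of that source, recovered 34% to 50% of 2-fold and 86% to 96% of 4-fold changes. With separate SDs, which the fit over all sources does not model, 14.9% to 22.4% of the calls between sources and 29.6% of the interaction calls were false. The simulation changed few probes and made log2 ratios directly, so its shares need not hold for the comparisons here. Alternatives covered the background correction, normalization, the scanner's processed values, the deposited table, Cy5 alone, filters, array weights, blocks, sample sets and each goat left out.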

Results

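Gene expression was measured in milk somatic cells (MSC), blood nuclear cells (PNCB) and milk fat globules (MFG) of 4 Polish White Improved (PWI) and 4 Polish Fawn Improved (PFI) dairy goats, each sample against a common blood reference. The labels set up 2 questions, how the RNA sources differ and whether the breeds differ. The share of the 43653 probes with Cy5 signal well above background was 56.3% ± 3.66 in MSC, 62.9% ± 2.55 in PNCB and 55.5% ± 15.5 in MFG (SD, n = 8 each). The wide spread in MFG came from PWI goats 2 and 4, at 84.6% and 75.3%, while the other MFG arrays lay between 44.1% and 51.5%. The share in Cy3, which held the same reference on every array, also differed, at 44.4% in MSC, 38.8% in PNCB and 61.1% in MFG. It was 88.0% and 71.5% on the MFG arrays of PWI goats 2 and 4. The Cy5 shares thus cannot be read as the sample RNA alone. The 100 brightest probes took 18.5% ± 2.32 of the net Cy5 signal in PNCB, 24.8% ± 3.06 in MSC and 35.9% ± 2.77 in MFG (SD, n = 8). Of all probes, 15155 (34.7%) were well above background on all 24 arrays. A set of 288 probes was well above background on all 16 milk arrays and on none of the 8 PNCB arrays, and 153 probes were so on all 8 PNCB arrays and on none of the 16 milk arrays.

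The RNA source held most of the variation. Over the 11555 probes measured on every array, source accounted for 69.6% of the sum of squares of the log2 ratios, breed for 1.88%, breed by source for 2.98% and the spread within groups for 25.5%. The spread within groups alone also gives breed and breed by source some share, more for the latter, and this was not subtracted. The log2 ratios had an SD across probes of 0.39 ± 0.15 in PNCB, 0.90 ± 0.03 in MSC and 1.16 ± 0.05 in MFG (SD, n = 8). The reference was itself blood RNA, so PNCB ratios lie near 0. The median SD between goats of a group was 0.20 in MSC, 0.29 in PNCB and 0.23 in MFG on the log2 scale, and 0.20 in both PNCB and MSC and 0.17 in MFG without the 3 arrays of low spike-in slope.

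**Figure D1:**
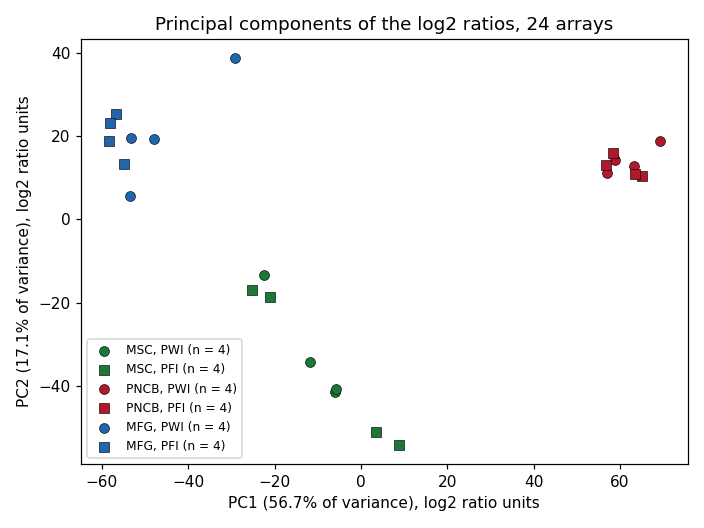
Principal components of the log2 ratios of the 11555 probes measured on all 24 arrays. The horizontal axis is PC1 (56.7% of the variance) and the vertical axis PC2 (17.1%), in log2 ratio units. Each point is 1 array, colour marks the source and shape the breed. PNCB arrays lie between 56.8 and 69.2 on PC1, MSC arrays between -25.2 and 8.86 and MFG arrays between -58.5 and -29.1.

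The first comparison set milk somatic cells against blood nuclear cells. Of 27381 probes tested, 6149 were higher and 7421 lower in MSC, 49.5% of all, with median log2 differences of 0.76 and -0.67. At least 2-fold, 1986 probes were higher and 2108 lower, and at least 4-fold 534 were higher and 417 lower. These counts depended on the scaling, with 2043 higher and 5063 lower at least 2-fold with median centring, and 4502 and 6659 with the scanner's processed values. Probe A_73_P038001 (NM_174187) had a mean log2 ratio of 5.98 ± 0.30 in MSC (SD, n = 8) and was not well above background on any PNCB array. The log2 difference of its ratios was 6.16 (SE 0.18, limma adjusted p = 1.49e-17). The fold was 71.5 in the ratios and 294 in the Cy5 channel after loess and Aquantile, where the PNCB signal lay near background. Probe A_73_114724 (NM_174299) had a mean of 6.36 ± 0.98 in MSC (SD, n = 8) and was likewise not well above background in PNCB. The log2 difference of its ratios was 6.32 (SE 0.48, limma adjusted p = 2.82e-10). Its fold was 80.0 in the ratios and 146 in the Cy5 channel after loess and Aquantile, with the same limit. Probe A_73_P441566 (NM_001014902) had a mean of -4.43 ± 0.27 in MSC against 0.94 ± 0.57 in PNCB (SD, n = 8 each), 41.2-fold lower in MSC (log2 difference -5.36, SE 0.17, limma adjusted p = 1.18e-16), and all 3 tested probes of its accession were lower, with a log2 difference of -2.90 for their mean. Probe A_73_P046111 (NM_001075234) was 24.6-fold lower in MSC (log2 difference -4.62, SE 0.21, limma adjusted p = 3.26e-14), and the mean of the 2 tested probes of its accession differed by -3.34. All of these had the same sign in 8 of 8 goats, which the naming rule required. Among 2781 accessions with at least 2 called probes, 2681 (96.4%) had all of them in one direction. The median of all probes lay at -0.04, and at -0.17 with median centring in place of loess. The RNA of the 2 sources was extracted with different kits. The count was 7721 within PWI goats alone and 10840 within PFI goats alone.

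The second comparison set milk fat globules against blood nuclear cells and gave the most calls. In MFG 6987 probes were higher and 10507 lower, 63.8% of those tested, with median log2 differences of 0.81 and -0.77. At least 2-fold, 2628 were higher and 3944 lower. These counts depended on the scaling, with 1290 higher and 12372 lower with median centring, and 4639 and 11045 with the scanner's processed values. With Cy5 alone they were 4249 and 5231. Probe A_73_P034886 (NM_001024569) had a mean log2 ratio of 6.96 ± 0.49 in MFG (SD, n = 8) and was not well above background on any PNCB array. The log2 difference of its ratios was 7.10 (SE 0.20, limma adjusted p = 1.22e-17). Its fold was 137.6 in the ratios and 503 in the Cy5 channel after loess and Aquantile, where the PNCB signal lay near background. Probe A_73_108260 (NM_001075120), well above background on 3 of the 8 PNCB arrays, was higher in MFG (log2 difference 7.08, SE 0.18, limma adjusted p = 9e-19). The size is uncertain, as its mean log2 Cy5 signal in PNCB, 6.13, lay near background. All 3 tested probes of its accession were higher, with a log2 difference of 4.93 for their mean. Probe A_73_P441566 (NM_001014902), named above, was 65.4-fold lower in MFG (log2 difference -6.03, SE 0.17, limma adjusted p = 4.83e-18), but only 2 of the 3 tested probes of its accession were called lower, and their mean differed by -3.08. Probe A_73_121104 (D90419) was 48.0-fold lower (log2 difference -5.58, SE 0.26, limma adjusted p = 6.73e-14). The naming rule required the same sign in 8 of 8 goats. Among 3659 accessions with at least 2 called probes, 3369 (92.1%) had all of them in one direction. With median centring in place of loess, the median of all probes lay at -0.82 against -0.13, and higher probes made up 19.3% of the calls against 39.9%. The count was 11467 within PWI goats alone and 16038 within PFI goats alone, and kit and scan day went with the source.

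The third comparison set both milk sources against each other. In MFG 3458 probes were higher and 6075 lower than in MSC, 34.8% of those tested. At least 2-fold, 361 were higher and 2168 lower, and at least 4-fold 38 were higher and 555 lower. Probe A_73_P036246 (NM_001098999) was 11.3-fold higher in MFG (log2 difference 3.50, SE 0.32, limma adjusted p = 5.23e-08), with a mean of 3.51 ± 1.11 in MFG against 0.01 ± 0.24 in MSC (SD, n = 8 each), and all 4 tested probes of its accession were higher, by 3.33 for their mean. Probe A_73_114883 (NM_001102278) was also higher (log2 difference 3.42, SE 0.36, limma adjusted p = 1.47e-07), and the mean of the 3 tested probes of its accession differed by 2.46. Probe A_73_P095346 (ENSBTAT00000038757), well above background on 7 of the 8 MFG arrays, was 29.3-fold lower in MFG (log2 difference -4.87, SE 0.47, limma adjusted p = 8.69e-08), and probe A_73_120005 (JX560188) 29.2-fold lower (log2 difference -4.87, SE 0.42, limma adjusted p = 2.19e-08). Higher probes made up 36.3% of the calls, against 4.70% with median centring, 22.6% with the scanner's processed values or the deposited table and 46.9% with Cy5 alone. The median of all probes lay at -0.02, and at -0.61 with median centring. They made up 50.6% with array weights, 46.0% without PWI goat 2, 28.4% without PWI goat 1, 28.8% without PWI goat 3, 29.2% without PFI goat 2, 8.49% within PWI goats alone and 49.7% within PFI goats alone. The count was 3367 within PWI goats, 9485 within PFI goats and 15383 with array weights. The higher calls numbered 2238 without PWI goat 1, 2014 without PFI goat 2 and 2287 without PFI goat 3. MFG arrays were scanned on another day.

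**Figure D2:**
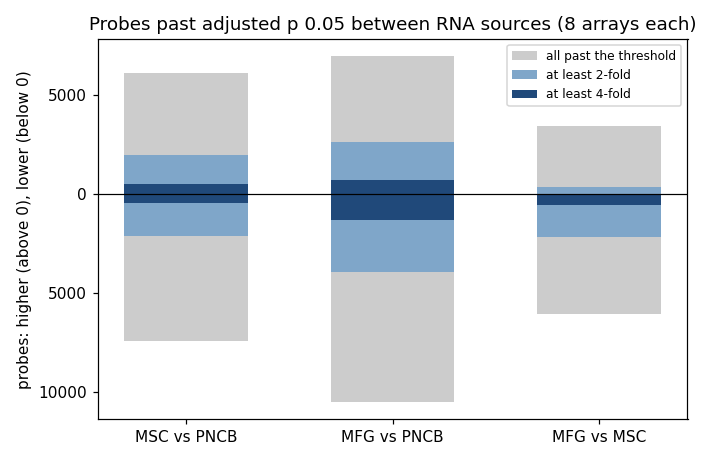
Probes past an adjusted p of 0.05 in the 3 comparisons of RNA sources, 8 arrays per source. Bars above 0 count probes higher in the source named first and bars below 0 those lower in it. Grey is all called probes and the blues are those at least 2-fold and at least 4-fold different, drawn from 0. The calls between MFG and MSC include 2168 probes at least 2-fold lower in MFG and 361 at least 2-fold higher.

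Of the probes tested, 4399 were higher and 6659 lower in both milk sources than in PNCB, and 436 had opposite calls. Independent lists of these sizes would share 1567 higher and 2845 lower probes, while unchanged groups simulated against the same blood arrays shared 0, a count that unchanged groups fix near 0. The log2 differences of the 2 comparisons correlated across probes at r = 0.811, against 0.501 in the simulation, with a covariance of 0.733 against 0.0141. Probes are not independent replicates. With no array in common, MSC against PNCB in one breed and MFG against PNCB in the other breed correlated at 0.762 and 0.768, with covariances of 0.755 and 0.676. MSC was higher than both other sources at 1652 probes, 548 of them at least 2-fold above each, and lower than both at 372 probes, 3 of them at least 2-fold below each. With the scanner's processed values 1141 probes were at least 2-fold above each and 140 at least 2-fold below each.

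The source differences were also measured in each breed separately, on disjoint arrays. They correlated across probes at 0.926 for MSC against PNCB, 0.944 for MFG against PNCB and 0.892 for MFG against MSC. Of 6278 probes called in both breeds for MSC against PNCB, 6275 had the same direction, as had 9870 of 9875 for MFG against PNCB and 3050 of 3050 for MFG against MSC.

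The breeds were compared within each source, 4 goats against 4. In MSC 0 probes passed the threshold by limma, with 1200 at an unadjusted p under 0.05 where chance gives about 1370, and with 2339 without PFI goat 1. In PNCB 3 probes passed, all higher in PWI, with 3.56% of probes at an unadjusted p under 0.05. Their number was 466 without PFI goat 2, 599 without PFI goat 1 and 1927 without PWI goat 4. Probe A_73_120401 (NM_174213) was 9.76-fold higher in PWI, with mean log2 ratios of 1.31 ± 0.19 (SD, n = 3) against -1.98 ± 0.09 (SD, n = 4; limma adjusted p = 0.000167). Probe A_73_107408 (NM_206843) was 6.12-fold higher in PWI, at 0.82 ± 0.18 (n = 3) against -1.79 ± 0.23 (n = 4; limma adjusted p = 0.00198). Probe A_73_105187 (NM_001075950) was 4.87-fold higher in PWI (log2 difference 2.28, SE 0.19, limma adjusted p = 0.00604). The spots of all 3 on the array of PWI goat 4 carried an outlier flag and were left out. At each of the 3 probes, the 3 PWI goats measured lay above all 4 PFI goats. That nearly follows from their being picked by the breed test and is no separate evidence. The other tested probe of NM_206843 differed by 0.30 on the log2 scale and was not called.

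In MFG 4 probes passed. An unadjusted p under 0.05 was reached by 2349 probes where chance gives about 1369, and 1873 of them were lower and 476 higher in PWI. The median difference of all tested probes was also below 0, at -0.13. It was -0.17 with Cy5 alone and -0.03 with array weights, which gave PWI goat 2 a weight of 0.13. The excess of lower probes cannot be told apart from this shift of all probes. The number at an unadjusted p under 0.05 was 4234 without PWI goat 1, 3824 without PWI goat 3 and 1460 without PWI goat 4. Without PFI goats 1, 2 and 4 it was 1318, 1507 and 1324. Probe A_73_107408 was again higher in PWI, 8.86-fold, at 2.12 ± 0.59 against -1.03 ± 0.32 (SD, n = 4 each; limma adjusted p = 0.0178). Both called probes of NM_001079789 were lower in PWI, A_73_P096351 6.79-fold (log2 difference -2.76, SE 0.15, limma adjusted p = 0.000897) and A_73_P261821 4.39-fold (log2 difference -2.14, SE 0.17, limma adjusted p = 0.0101). Probe A_73_P118486 (X64897) was 6.42-fold lower in PWI (log2 difference -2.68, SE 0.25, limma adjusted p = 0.0178). The 4 PWI goats lay on one side of the 4 PFI goats at each of these probes, which again nearly follows from how they were picked. The other tested probe of NM_206843 differed by 0.03. With outlier-flagged spots kept in the background fit and left out after it, 0 probes passed by limma in PNCB and 0 in MFG, with 787 and 674 at an unadjusted p under 0.05. The 7 differences kept their direction there, for example a log2 difference of 2.70 at A_73_120401 and of -1.79 at A_73_P096351, at adjusted p of 0.859 and 0.938. In MFG 28 probes passed without PWI goat 2, and 1 or 2 without PWI goat 3 or any PFI goat.

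**Figure D3:**
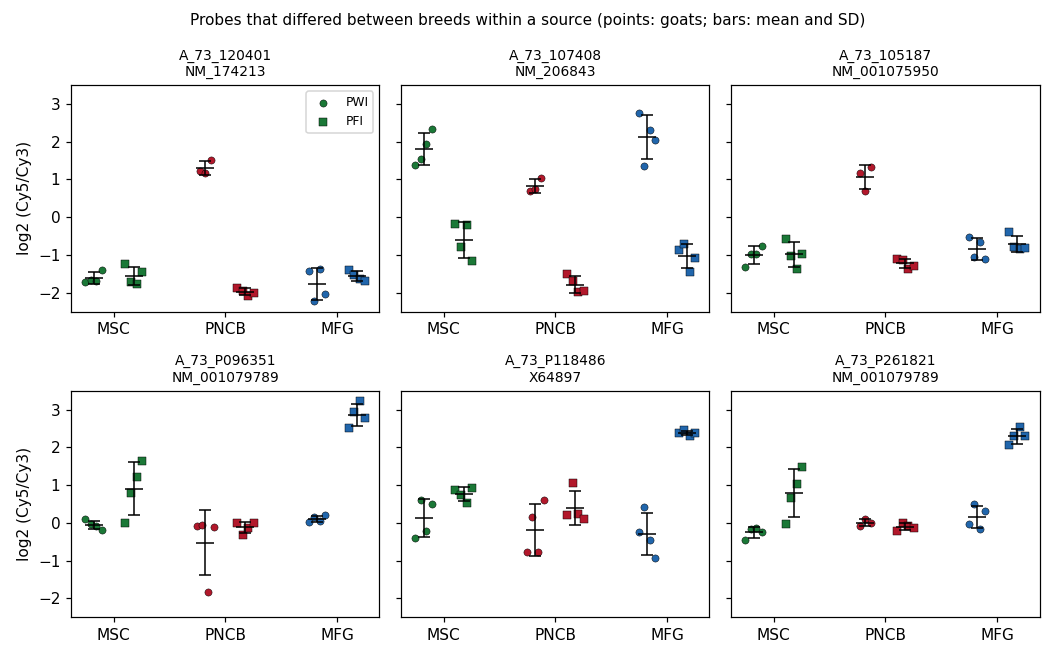
Log2 ratios of Cy5 over Cy3 of the 6 probes that passed the threshold between breeds within a source. Each point is 1 goat (circles PWI, squares PFI), colours mark the sources, and black bars give the mean and SD of each group. Probe A_73_107408 is higher in PWI in every source, with a log2 difference of 2.61 in PNCB and 3.15 in MFG past the threshold and of 2.39 in MSC with an adjusted p of 0.301.

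Over the 3 sources, with 1 mean per goat, A_73_107408 was the 1 probe that passed, 6.35-fold higher in PWI (log2 difference 2.67, SE 0.16, limma adjusted p = 0.000433). That call rested on 3 PWI and 4 PFI goats, as PWI goat 4 had no PNCB value for this probe. In MSC its difference was 5.26-fold and did not pass (log2 difference 2.39, SE 0.28, limma adjusted p = 0.301). As measured, the 95% interval of the breed difference lay within 2-fold in either direction for 92.2% of probes in MSC, 86.9% in PNCB, 80.6% in MFG and 99.1% over the 3 sources. These shares include probes near background in a source, whose ratios the offset draws toward 0, and for these they set no bound. Of the 27411 tested probes, 20631 were well above background on all 8 MSC arrays, 24047 on all 8 PNCB arrays and 16519 on all 8 MFG arrays. The breeds sat on different slides in every source, so slide and breed cannot be told apart within a source. Over the 3 sources the count was 6 without PWI goat 2, 3 without PFI goat 1 and 2 without PFI goat 2, and it ranged from 0 to 14 with the alternatives.

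The interaction of breed and source passed at 3 probes by limma's F-test, with 1675 at an unadjusted p under 0.05. That number was 3052 without PWI goat 1, 1101 without PFI goat 1 and 852 without PFI goat 2. Probe A_73_120401 differed between breeds by 3.29 on the log2 scale in PNCB, by -0.06 in MSC and by -0.20 in MFG (adjusted p = 5.38e-08). Probe A_73_105187 differed by 2.28 in PNCB, -0.02 in MSC and -0.13 in MFG (adjusted p = 0.000105). Probe A_73_P261821 differed by -2.14 in MFG, -1.04 in MSC and 0.11 in PNCB (adjusted p = 0.0219). Array weights gave 25 interaction calls. The count was 6 without PWI goat 3 or PFI goat 4 and 5 without PWI goat 4.

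The Cy3 channel, which held the same reference on every array, gave 0 probes past the threshold by limma between the slides of the breeds, with 2213 (8.08%) at an unadjusted p under 0.05 where chance gives about 1370. Normalized alone it also gave 0 probes, with 10.6% at an unadjusted p under 0.05. Between sources it differed more. Normalized alone, Cy3 differed at 10440 probes between MFG and PNCB arrays, at 10818 between MFG and MSC arrays and at 599 between MSC and PNCB arrays. Over the probes called in MFG against PNCB, the median absolute log2 difference was 0.15 in Cy3 and 1.06 in Cy5 normalized alone.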

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

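The tests of a mixture in milk somatic cells and of other probes of the same transcript were chosen after the results they bear on had been seen.

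In 118 groups of 4 values (array measures and named probes), 6 held a sample far from the other 3, where chance gives about 5.9. The share of net signal in the 100 brightest probes was 27.8% in MSC of PWI goat 4 against 23.8% to 23.9% in the others. The log2 ratio of A_73_P441566 was -3.86 in MSC of PFI goat 1 against -4.71 to -4.61. That of A_73_120401 was -1.39 in MSC of PWI goat 4 against -1.72 to -1.67. That of A_73_105187 was -0.40 in MFG of PFI goat 1 against -0.84 to -0.80. That of A_73_P096351 was -1.82 in PNCB of PWI goat 3, an array of low spike-in slope, against -0.11 to -0.06. That of A_73_P118486 was 1.06 in PNCB of PFI goat 2 against 0.09 to 0.23. The breed difference changed with the source, by the interaction test, at 3 probes.

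Other splits of the samples were counted. Swapping the labels of both sources within goats, 1 of 100 splits, the real one, reached the count in each comparison of sources. MSC against PNCB gave 13570 probes and at most 9433 otherwise, MFG against PNCB 17494 and at most 13913, and MFG against MSC 9533 and at most 7335. Chance can thus be excluded for these counts. Those highest others swapped 1 goat, and with 4 goats swapped the highest counts were 0, 6 and 0. Of the 35 splits of the 8 goats, 1, the smallest number possible, reached the 3 probes of the breeds in PNCB (highest other 2) and 1 the 4 probes in MFG (highest other 0). That is 2.86% of the splits for each count, which does not exclude chance, as several breed counts were tested. The processing used was also settled after counts of 0 had been seen. Both counts were 0 with outlier spots kept in the background fit and with goat number as a replicate block. Chance cannot be excluded over the 3 sources either, where 2 of 35 splits gave at least 1 probe (highest other 1). Nor can it be for the interaction, where 6 of 35 gave at least 3 (highest other 114). The 0 probes of the breeds in MSC were reached by 35 of 35 splits. The highest of these, 3044 probes, set goats 1 and 4 of both breeds against goats 2 and 3, which points to a structure of the MSC samples. Those numbers are also the outer and inner positions on the slides. The MSC arrays of goats 1 and 4 were also the nearest to MFG when other goats' PNCB was set at 0 and MFG at 1. They stood at 0.613 to 0.750, and those of goats 2 and 3 at 0.441 to 0.563. What underlies the split was not tested. The same split gave 0 probes in PNCB, 0 in MFG and 0 in Cy3 of the MSC arrays. For the Cy3 reference between breed slides, 100 of 100 splits reached 0 (highest other 1).

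Milk fat globules differed from both other sources, less from MSC than from PNCB. Their arrays were scanned on a separate day, but a scan day or slide effect that reaches both channels should move the shared reference too. Over the probes called against PNCB the reference moved 0.147 times as far as Cy5. Those probes were picked by their ratio, in which an effect alike in both channels cancels, so this share cannot decide on one. Over all tested probes, each channel normalized alone, the median absolute log2 difference from PNCB was 0.14 in Cy3 and 0.67 in Cy5. This argues against an effect alike in both channels as the whole cause, though the reference did differ at 10440 probes. An effect in Cy5 alone, the extraction kit against blood and the source itself stay open. The excess of strongly lower over strongly higher probes against MSC depended on the scaling, at 6.01 as reported, 6.53 with processed signals, 188 with median centring and 1.75, under a limit of 2 set beforehand, with Cy5 alone, which also drops the reference, so the share of the within-array normalization cannot be told apart. Without the arrays of low spike-in slope, which were picked after seeing the data, it was 3.5, above a limit of 2 written before that ratio was computed, so they are not its whole cause. It was 3.56 without PWI goat 2, 2.46 within PFI goats and 17 within PWI goats.

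Milk somatic cells lay between blood cells and milk fat globules when averaged over probes, with all 3 comparisons called in that order at 1608 rising and 2118 falling probes, and outside both at 1652 and 372. With other goats' PNCB at 0 and MFG at 1, MSC arrays stood at 0.605 ± 0.114 (SD, n = 8, from 0.441 to 0.750), with 0.614 in PWI and 0.595 in PFI (exact permutation test, two-sided, p = 0.886). MFG arrays stood at 0.929 in PWI and 1.04 in PFI (exact permutation test, two-sided, p = 0.0286, the smallest possible), with PWI goat 2 at 0.756. A mixture of RNA like that of both other sources should leave few probes outside both, on either side, but 183 times as many were at least 2-fold above both (548) as at least 2-fold below both (3). That ratio was 98.1 with median centring, 28 with Cy5 alone and 8.15 with processed signals, below the 10 set afterwards as a limit. Under every setting tried, 450 to 1142 probes lay at least 2-fold above both and 3 to 140 at least 2-fold below both. More probes thus lay above both than below both under each setting. The ratio was below 10 with processed signals and with the deposited table (8.34), so the limits, set afterwards, do not decide on a mixture alone. A mixture alone, other cells in milk and a change of the cells there, the last untested, cannot be told apart.

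The 7 breed calls within PNCB and MFG were set against technical explanations. Their reference differed 0.0766 times as far as their ratio. A slide effect alike in both channels cancels in the ratio by which these probes were picked, so this value cannot decide on one. The arrays of low spike-in slope are argued against, as 100% of these calls stayed without them, though the 3 calls in PNCB never used the array of goat 4. The call over the 3 sources, with 1 PWI goat left, was lost at a log2 difference of 2.75 against 2.67 (limma adjusted p = 0.146). At NM_206843 the other tested probe moved 0.0624 times as far as the called one, consistent with a sequence variant under the probe, while at NM_001079789 the probe not called, A_73_117639, differed by -1.48 (SE 0.20), 0.613 times as far, which argues against a variant as the whole cause there. At NM_001075950 the share was 0.296, between the limits set, and NM_174213 and X64897 had no other tested probe. A slide effect and a true breed difference stay open.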

How the results depend on the processing

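The alternatives without the 3 arrays of low spike-in slope and with spots marked as outliers kept in the background fit were chosen after seeing the data, and all others before the data were examined. Under alternatives 54 counts differed from the reported one by more than 1.5 times, and for each the cause was not tested unless stated. Aquantile changes no ratio and so tests nothing. The 12 probe results named between sources kept direction and call under each alternative that gave a value. Of the named breed results, 40 values lost the call with the same direction. With goat as a fixed replicate block the source counts were 13169, 17085 and 9305 (MSC against PNCB, MFG against PNCB, MFG against MSC) and the interaction 4, so the pairing changed no count by over 1.5 times. Number is shared across breeds without pairing animals, and as a replicate block it gave 0 breed calls in MSC, 0 in PNCB, 0 in MFG and 2 over the 3 sources, with differences of similar size (A_73_120401 3.27 against 3.29, A_73_P096351 -2.76 in both). Deviations of equal numbers across breeds correlated at a mean of 0.303 in MSC (3 of 4 pairs over 0.1), -0.245 in PNCB and 0.0466 in MFG, and 0, 0 and 1 of 4 PWI arrays correlated best with their own number. Requiring signal in both channels on all arrays left 5501 probes between sources, hence fewer calls: 3702, 4380 and 3169 between sources, and 0 in PNCB, 0 in MFG and 0 over the 3 sources between breeds. Between sources these were larger shares of the probes tested than those reported. The probes called between breeds were not among those left, so these counts of 0 are no retest of them. Within PWI goats alone, who hold the 3 low-slope arrays, the counts were 7721, 11467 and 3367, and within PFI goats alone 10840, 16038 and 9485. MFG against MSC gave 18207 with median centring, 15383 with array weights and 5165 with outlier spots kept. Breed in MSC gave 1 with all 24 arrays in one fit. Breed in PNCB gave 7 with processed ratios, 5 with the deposited table, 9 with all 24 arrays, 6 without the low-slope arrays and 0 with outlier spots kept. Breed in MFG gave 2 with median centring, 1 with Cy5 alone, 35 with array weights, 42 with all 24 arrays, 28 without the low-slope arrays and 0 with outlier spots kept. Breed over the 3 sources gave 2 without background subtraction, 3 with median centring, 14 with processed ratios, 14 with the deposited table, 7 with array weights, 7 with slide and 6 with goat as a random block, and 0 without the low-slope arrays, where PWI keeps 1 goat that is assumed to vary like the PFI goats. The interaction gave 6 with processed ratios, 6 with Cy5 alone, 7 with the deposited table, 25 with array weights, 22 without the low-slope arrays and 1 with outlier spots kept. Cy3 between breed slides gave 4 without the low-slope arrays. Leaving out each goat gave 11766 to 13749, 16084 to 17892 and 6886 to 10153 between sources, 0 to 0 in MSC, 2 to 4 in PNCB, 1 to 28 in MFG, 1 to 6 over the 3 sources and 2 to 6 for the interaction. In MFG the 28 came without PWI goat 2, and 1 or 2 without PWI goat 3 or any PFI goat. Over the 3 sources 6 came without PWI goat 2, 3 without PFI goat 1 and 2 without PFI goat 2. For the interaction 6 came without PWI goat 3 or PFI goat 4 and 5 without PWI goat 4. The gene list results and their alternatives were not run, as probes have no gene names here, and the alternative that averages the probes of a gene used those of its accession. Signal over background limits the weak probes, whose ratios the offset draws toward 0.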
